A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

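RNA was extracted from skin and sequenced from Illumina libraries, per the labels' protocols, in 3 control samples and 3 samples taken 48 h after viral challenge. Bowtie2 2.2.8 and TopHat2 2.1.1 are named per the submitters' processing notes; the read counter, genome build and annotation are not given in the sources used here. The authors deposited 1 table with, per the file headers, read counts and FPKM for each library (counts per gene, and the same divided by transcript length and library size), group means of FPKM, log2 fold change, p-value and FDR. In the authors' deposited table the log2 fold change equals the log2 ratio of the mean FPKM values, with 0.001 in place of a mean of 0, its smallest absolute value is 1 and the largest FDR is 0.0499, so the table holds called genes only: 6905 genes, 2533 higher and 4372 lower in infected skin. The authors' p-value and FDR at rank 200 imply that 39213 genes were tested (39195 at rank 500), and 28.9% of those had an FDR under 0.05. Genes outside the table are not analysed here. Columns of samples of another series numbered 0.

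Gene IDs are those of the table, of which 443 carry MSTRG identifiers, and names and descriptions are the authors' homolog annotation, present for 5991 genes. Of the IDs, 4595 are also in the RefSeq gene table of assembly USDA_OmykA_1.1, which was used only for this count. No coordinates are printed because the build is not given in the sources used here.

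The test had been fixed before the data were examined as limma on log2(FPKM + 1), with edgeR's quasi-likelihood test in its place should the table hold counts, which it does. Normalization factors computed from called genes would take most of them as unchanged. Library sizes were therefore recovered from the deposited counts and FPKM: for genes with at least 200 counts and 5 FPKM, the ratio of count to FPKM relative to control replicate 1 gave relative library sizes of 1.00, 1.07 and 1.05 (controls) and 1.06, 1.25 and 0.998 (infected), with at least 91.8% of genes within 1% of the median ratio. This keeps the authors' scaling. EdgeR 4.0.16 (R 4.3.3) tested genes with a mean of at least 1 FPKM over the 6 libraries, 5489 genes, with no covariate. The tests are two-sided, Benjamini-Hochberg adjusted over the genes tested, with 0.05 as threshold. Adjusting over genes that were already selected makes adjusted p-values too small, so counts were also adjusted over 39213 tests. Standard errors are the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 0.178. A group with 0 counts was given a floor of 3 counts over the group, and for 1 to 3 counts an exact 95% binomial interval of the ratio was taken. Replicates of a group differed by more than counting noise (chi-square per gene 8.72 to 32.6), which separate libraries of 1 sample could do as well; each was treated as a sample, as labelled.

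On simulated counts with the real means, library sizes and dispersions, edgeR recovered 80% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold for the comparison of infected with control libraries over 5489 genes, with 8 calls among 5289 unchanged genes. Most genes were unchanged in that simulation, whereas almost all tested genes of the real table passed, so its recovery does not carry over as a limit. The authors' selection itself sets a limit of a 2-fold change.

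There were 22 gene lists, set as name patterns before the data were examined: viral RNA sensing, interferon-stimulated genes, MHC class I and class II presentation, cytokines and chemokines, cytokine signalling brakes, antimicrobial and acute phase, complement, T and cytotoxic lymphocyte, B cell, myeloid, skeletal muscle, epithelium and keratinocyte, mucus and secretory, pigment cell, collagen and extracellular matrix, erythrocyte, cell cycle, mitochondrial respiration, cytosolic ribosomal proteins, immediate early and heat shock, and cell death. Some patterns matched other genes, such as S6 kinases or C1q-like proteins; these were removed by name as an alternative chosen after seeing the data. Lists of at least 5 tested genes were tested by camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated one, and by fry, Benjamini-Hochberg adjusted over the lists.

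Named genes followed a rule set before the data were examined: the 5 risen and 5 fallen genes with the largest absolute log2 fold change among called genes with a name, a mean of at least 5 FPKM in the higher group and no overlap between groups; the 2 members with the smallest p in the sensing, interferon-stimulated, MHC class I, cytokine, antimicrobial and complement lists; and 1 in each other list. Members were taken from the lists without mismatched names. Other genes named as examples were chosen after their values were seen.

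Alternatives were limma on log2 of FPKM plus 1, 0.1 or 0.5, no filter, a mean of 5 FPKM, TMM, DESeq2 size factors, DESeq2 1.42.0, median-ratio and quantile scaling, limma without trend or with array weights, an added fold threshold, the replicate number as a block, and leaving out each library. Limma on log2(FPKM + 1), fixed beforehand only as the test for a table without counts, was kept as an alternative beside edgeR after the table was seen to hold counts. The adjustment over the authors' tests and, for gene lists, a mean of 5 FPKM, TMM, DESeq2 size factors, pseudocount 0.5, no trend and array weights were added after seeing the data; limma alternatives change the tool as well as the setting.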

Results

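RNA sequencing was done on skin of rainbow trout (Oncorhynchus mykiss) taken 48 h after challenge with infectious hematopoietic necrosis virus, a rhabdovirus of salmonid fish, and on skin of control fish. Each group held 3 samples, and all were labelled wild-type. The deposited table listed 6905 genes, the number the submitters state as differentially expressed, with read counts and FPKM per library. Over these genes the control libraries held 2449233 to 2452794 counts and the infected libraries 4084344 to 5188055 counts. These totals cover only the listed genes and are not the full depth of the libraries. Log2(FPKM + 1) values correlated at 0.979 to 0.987 (Pearson's r across genes) between libraries of one group and at 0.617 to 0.696 between groups, over genes the authors had selected for differing between these groups. No label says that the samples of a group came from separate fish, so p-values here measure the spread between these samples, which may be technical.

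The comparison asked which skin transcripts differed between infected and control trout. In infected skin, listed genes of antiviral sensing, the interferon response, cytokines and chemokines, and antigen presentation mostly rose. So did those of the joint immediate early and heat shock list. The antiviral gene vig1 went from 2.84 ± 0.270 to 804 ± 34.7 FPKM (mean ± SD, n = 3 per group) and the chaperone gene hsp90a.1 (LOC110529844) from 7.64 to 320 FPKM. Listed genes of the extracellular matrix, epithelium, cell cycle and red blood cells mostly fell, by smaller factors, such as mcm6 from 23.1 ± 3.24 to 5.67 ± 0.646 FPKM. Of 5489 listed genes with a mean of at least 1 FPKM, 5482 changed, of which 2015 rose and 3467 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was 1.98 among risen and -1.41 among fallen genes. Changes of at least 8-fold were found for 508 risen and 50 fallen genes. A rise of at least 32-fold was found for 131 tested genes, with the 13 that had no control count taken at their lower bound. No tested gene fell by that much, and listed genes under the filter are not counted here. The FPKM ranges of the groups did not overlap for 5439 genes (99.1%), against 10% by chance for 3 samples against 3. All of these genes had been selected by the authors on the same 6 libraries, with an absolute log2 fold change of at least 1, so neither the counts of risen and fallen genes nor their directions are independent evidence of a change, and genes that did not change are not in the comparison. Adjusted over the 39213 genes that the authors' p-values and FDR values imply were tested, 5393 genes changed, 1926 up and 3467 down. Falls made up 63.2% of the changed genes, but 35.9% when libraries were scaled by DESeq2's size factors over the listed genes, where 2022 rose and 1130 fell, and 33.6% with median-ratio scaling of FPKM tested by limma, where 2018 rose and 1020 fell. Those scalings take most genes as unchanged. The main scaling keeps the recovered library sizes without a further factor, so reads taken up by risen genes would lower the share of other genes. Which of these scalings is right cannot be told from the listed genes. Falls stayed the larger part with TMM over the listed genes, at 58.9% (2022 rose, 2893 fell). With quantile normalization, tested by limma, they were 62.3% (1852 rose, 3063 fell). In edgeR, DESeq2's size factors raised the median log2 fold change of all tested genes by 1.06 and TMM raised it by 0.72, and in limma on log2(FPKM + 1) median-ratio scaling moved it from -0.85 to -0.039. With a mean of at least 5 FPKM required, 2473 genes changed, 1340 up and 1133 down.

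Among the genes with the largest rises were antiviral effectors and a cytokine receptor. The 2 genes annotated as rsad2 (viperin, an interferon-induced enzyme that blocks replication of many viruses) rose most among genes with over 3 control counts. LOC110498119 went from 0.763 ± 0.0945 to 269 ± 43.0 FPKM (mean ± SD, n = 3 per group), a log2 fold change of 8.46 ± 0.23 (SE) with an adjusted p of 4.08e-09 (edgeR, Benjamini-Hochberg), and vig1 had a log2 fold change of 8.14 ± 0.19. LOC110497177, annotated as interferon-inducible Gig2-like, had 0 counts in the 3 control libraries and 526 in the infected ones, so it was at least 166-fold higher, taking a floor of 3 counts over the group. One gene annotated as aste1 (asteroid homolog 1), LOC110513255, had 0 control and 256 infected counts and was at least 80.6-fold higher. Another, LOC110511524, had 3 control and 1206 infected counts, a ratio of 380 with a 95% exact interval of 130 to 1844. MSTRG.14426, annotated as the interleukin-22 receptor subunit alpha-1, had 1 control and 478 infected counts, a ratio of 452 (95% exact interval 80.7 to 17872). Such intervals and floors cover counting error only.

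Among genes with a name, a mean of at least 5 FPKM in the higher group and no overlap between groups, the 5 that fell most included a matrix, an adhesion and a skin barrier gene. EMILIN3 (LOC110492516), an elastin-associated glycoprotein, fell from 12.7 ± 1.22 to 0.520 ± 0.0625 FPKM, a log2 fold change of -4.61 ± 0.18. The integrin subunit itga8 changed by -4.10 ± 0.24, and ALOXE3 (LOC110517354), an epidermal lipoxygenase of the lipid barrier, by -3.90 ± 0.32. LOC110486952, annotated as nuclear GTPase SLIP-GC-like, changed by -3.88 ± 0.23, and MSTRG.43679, annotated only as a protein kinase, by -3.64 ± 0.73. MSTRG.43679 had only 63 control and 5 infected counts, so its fold is less certain. Adjusted p-values of these 5 genes were at most 5.11e-04 (edgeR, Benjamini-Hochberg).

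**Figure D1:**
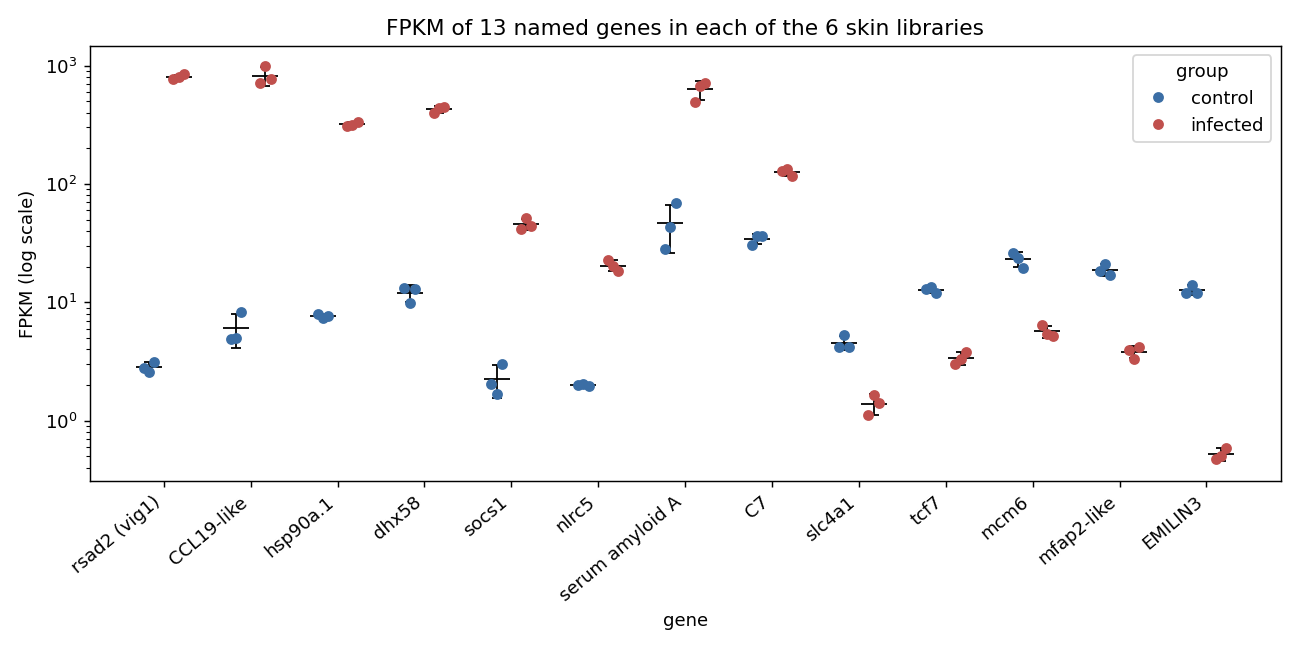
FPKM (log axis) of 13 named genes in each of the 3 control (blue) and 3 infected (red) skin libraries. Points are libraries, horizontal marks are group means and bars are ± SD; for each gene the infected libraries lie all on one side of the controls, as for vig1 with means of 2.84 and 804 FPKM.

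Genes of the viral RNA sensing list, most of them annotated as TRIM25, and interferon-stimulated genes rose almost without exception among the listed genes. All 83 tested members of the viral RNA sensing list rose, with a median log2 fold change of 2.50. The helicase dhx58 (LGP2), a regulator of RIG-I-type sensing, reached 427 ± 28.5 FPKM in infected skin (log2 fold change 5.15 ± 0.18), and the DNA sensor Cgas (LOC110489275) rose from 1.49 ± 0.145 to 36.7 ± 4.02 FPKM (4.62 ± 0.18). The RNA helicase mda5 rose by 2.84 ± 0.15 on the log2 scale, and the endosomal receptor for double-stranded RNA, tlr3, by 2.56 ± 0.14. The list was carried mostly by 1 annotation. Of the 81 members left after removing mismatched names, 66 were annotated as TRIM25, with a median of 2.41. The other 15 had a median of 2.93. TRIM25 is an E3 ligase that activates RIG-I, but here the name is a homolog symbol or description. LOC110516932, a listed gene under the filter, has the symbol TRIM25 but is described as tripartite motif-containing protein 16-like. The 66 genes were not shown to act in RNA sensing, and the list's counts and camera result rest mostly on them. Of 110 matches to the interferon-stimulated list, 108 rose and 2 fell, with a median of 3.50. Of the 109 left after removing mismatched names, 107 rose and 2 fell. Besides vig1, IFIT5 (LOC100135996) rose from 34.4 ± 5.11 to 1546 ± 54.5 FPKM (5.48 ± 0.18), and Cmpk2 rose by 5.21 ± 0.18. The members that fell were Ifitm5 (LOC110490850, -1.96 ± 0.34), whose mammalian homolog is a bone protein, and an IFI44L copy (LOC110528881, -1.41 ± 0.34). Against the other listed genes, both lists stood higher by camera (Benjamini-Hochberg adjusted p = 1.65e-20 for sensing and 1.75e-42 for interferon-stimulated genes), with adjusted p = 0.0769 for each with an estimated correlation. No sensing gene changed sign under any other scaling, and 5 interferon-stimulated genes did so under quantile normalization.

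Antigen presentation genes of the MHC class I pathway mostly rose as well. Of 36 tested members 34 rose and 2 fell, with a median log2 fold change of 1.53. The transactivator nlrc5, which drives MHC class I transcription, rose from 2.01 ± 0.0551 to 20.4 ± 2.17 FPKM (3.35 ± 0.15), and the tapasin-related LOC110500638 rose by 3.16 ± 0.16. The peptide transporter genes TAP1 (LOC110487866) and TAP2 (LOC110496230) rose by 2.55 ± 0.15 and 3.77 ± 0.24. The falls were in a calreticulin copy (LOC110508839, 13.8 to 6.87 FPKM) and a PDIA3 copy (LOC110513534, -1.44 ± 0.30), both endoplasmic reticulum chaperones. The list stood above the other listed genes by camera (Benjamini-Hochberg adjusted p = 3.52e-08), with adjusted p = 0.0769 with an estimated correlation, and under quantile normalization 6 members changed sign. Only 4 genes of the MHC class II list were tested, too few for camera. Of these, 3 genes annotated as CD83 (a maturation marker of dendritic cells) rose, LOC110514021 from 1.47 ± 0.391 to 73.2 ± 4.64 FPKM (5.64 ± 0.22), and the MHC II transcription factor RFX5 changed by -1.22 ± 0.20.

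Of 49 tested cytokine and chemokine matches 38 rose, 10 fell and 1 did not pass, with a median log2 fold change of 2.08. Left to genes that are cytokines by name, the counts were 30 risen and 9 fallen of 40. LOC110525193, like CCL19 (a ligand that guides dendritic cells and T cells), rose from 6.07 ± 1.95 to 824 ± 148 FPKM (7.08 ± 0.28), and cxcf1b, annotated as CXCL11 (an interferon-induced chemokine), from 10.5 ± 2.43 to 158 ± 16.9 FPKM (3.91 ± 0.20). The type I interferon gene ifna3 (LOC110538042) rose by 3.28 ± 0.26 and il6 (LOC110496949) by 4.88 ± 0.57. Among the falls were ccl13 (-2.76 ± 0.30), a CCL25-like gene (LOC110530809, -2.05 ± 0.26) that started at 366 FPKM, and nos2 (-2.60 ± 0.38), the inducible nitric oxide synthase. The cytokine list stood higher by camera (Benjamini-Hochberg adjusted p = 2.45e-05), with adjusted p = 0.203 with an estimated correlation and 0.0772 with a mean of at least 5 FPKM (range over alternatives 1.43e-06 to 0.203); 1 member changed sign under another scaling. Feedback inhibitors of cytokine signalling also rose, 13 of 14 (camera, Benjamini-Hochberg adjusted p = 0.00307; adjusted p = 0.326 with an estimated correlation). Socs1, which blocks JAK kinases, went from 2.25 ± 0.697 to 45.9 ± 5.05 FPKM (4.35 ± 0.22), and Tnfaip3 rose by 2.23 ± 0.16. Under quantile normalization 5 of these 14 genes changed sign, and adjusted p was 0.0653 there and 0.102 with a mean of at least 5 FPKM (camera, Benjamini-Hochberg, range over alternatives 3.41e-04 to 0.326).

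All 14 tested matches to the antimicrobial and acute phase list rose, with a median log2 fold change of 2.50, and none changed sign under another scaling. The 13 that are such genes by name had a median of 2.66. Lyg1 (LOC110505449, goose-type lysozyme) rose from 8.01 ± 0.266 to 38.1 ± 6.97 FPKM (2.25 ± 0.17), and serum amyloid A (Saa3, LOC110506659) from 46.4 ± 20.4 to 628 ± 118 FPKM (3.76 ± 0.31). Hepcidin (hamp1, LOC100135935), the iron-regulating peptide, rose by 5.99 ± 0.53, and the cathelicidin LOC100136187 reached 6140 FPKM from 1228 (2.33 ± 0.34). The camera test gave an adjusted p of 5.32e-04 (Benjamini-Hochberg), adjusted p = 0.135 with an estimated correlation and 0.0973 with a mean of at least 5 FPKM (range 3.75e-05 to 0.135). Of 22 matches to the complement list 15 rose and 7 fell, and of the 11 that are complement genes by name 10 rose and 1 fell. Component C7 (c7-1), part of the membrane attack complex, rose from 34.6 ± 3.32 to 127 ± 9.39 FPKM (1.88 ± 0.14) and C4A (LOC110517895) from 4.04 ± 0.295 to 16.6 ± 3.54 FPKM (2.03 ± 0.21), while the C5a receptor c5ar1 (LOC110504024) fell (-2.09 ± 0.30). Complement passed camera narrowly (Benjamini-Hochberg adjusted p = 0.0393), with adjusted p = 0.381 with an estimated correlation, and passed in 14 of 20 camera alternatives (adjusted p 0.0153 to 0.381). It did not pass without control replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0508).

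Genes of the joint immediate early and heat shock list and of the cell death list moved in both directions, with more rises than falls. Of 36 immediate early and heat shock genes 29 rose and 7 fell. The chaperone gene hsp90a.1 (LOC110529844) went to 320 ± 14.3 FPKM from 7.64 (5.39 ± 0.16), and hsp70b rose by 4.08 ± 0.21. Copies of the distant HSP70 relative HSPA12A went both ways: both tested copies fell, LOC110528078 by 3.04 on the log2 scale, while 3 listed copies under the filter had more counts in infected skin, such as LOC110487049 with 1 control and 115 infected counts (ratio 109, 95% exact interval 19.1 to 4328). Camera gave an adjusted p of 3.43e-05 (Benjamini-Hochberg), and adjusted p = 0.172 with an estimated correlation; at most 2 members of this list or of the cell death list changed sign under another scaling. Of 28 cell death matches 17 rose and 11 fell, and of the 25 that are cell death genes by name 14 rose and 11 fell. Cflar, an inhibitor of caspase-8, rose from 2.92 ± 0.427 to 28.8 ± 2.21 FPKM (3.25 ± 0.17), and caspase-8 itself (MSTRG.1163) rose by 3.22 ± 0.19. The cell death list passed narrowly (camera, Benjamini-Hochberg adjusted p = 0.0476; adjusted p = 0.326 with an estimated correlation) and in 10 of 20 camera alternatives (0.0250 to 0.326). It did not pass without control replicate 1 (0.0638), control replicate 2 (0.0531) or infected replicate 2 (0.0506), nor with matches that are other genes by name removed (0.0901).

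Structural genes of dermis and epidermis mostly fell in infected skin. Of 64 collagen and extracellular matrix matches 59 fell and 5 rose, with a median log2 fold change of -1.32. Of the 63 that are matrix genes by name 59 fell and 4 rose. Mfap2 (LOC110528061), a protein of elastic microfibrils, fell from 18.9 ± 2.08 to 3.81 ± 0.434 FPKM (-2.31 ± 0.17), the collagen I gene col1a2 from 629 to 251 FPKM (-1.32 ± 0.15) and sparc from 774 to 310 FPKM (-1.32 ± 0.14). The list stood below the other listed genes by camera (Benjamini-Hochberg adjusted p = 8.68e-04), with adjusted p = 0.381 with an estimated correlation. Scaled by DESeq2's size factors over the listed genes, 13 of the 59 falls passed, the median was -0.26 and 3 genes changed sign (7 with median-ratio scaling). With TMM 48 of the 59 falls passed and with quantile normalization 51, where 1 gene changed sign. All 16 listed red blood cell genes fell in the same libraries. Of 20 epithelial and keratinocyte matches 17 fell and 3 rose. The desmosome gene DSP (LOC110524668) fell from 66.4 to 16.7 FPKM and a type I keratin, krt13 (LOC110485898), from 366 to 120 FPKM (-1.61 ± 0.17), whereas the tight junction gene CLDN1 (LOC110534540) rose from 0.673 ± 0.340 to 16.4 ± 3.16 FPKM (4.59 ± 0.31). The epithelial list passed narrowly (camera, Benjamini-Hochberg adjusted p = 0.0450; adjusted p = 0.381 with an estimated correlation) and in 12 of 20 camera alternatives (0.00288 to 0.381). It did not pass camera without control replicate 1 (0.0534) or infected replicate 1 (0.0714). With mismatched names removed (15 of 18 fell) its camera adjusted p was 0.0692 (Benjamini-Hochberg). With DESeq2's size factors over the listed genes 10 of the 17 falls passed and 1 gene changed sign. With TMM 14 of the 17 falls passed and with quantile normalization 16, where 2 genes changed sign.

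All 55 tested genes of the cell cycle list fell, with a median log2 fold change of -1.39 and a range of -2.35 to -1.01. The replicative helicase gene mcm6 went from 23.1 ± 3.24 to 5.67 ± 0.646 FPKM (-2.03 ± 0.16), pcna (LOC110536211), the sliding clamp of DNA polymerase, from 45.2 to 13.7 FPKM (-1.73 ± 0.16), and rrm2 (LOC110529451), which supplies deoxynucleotides, from 111 to 33.5 FPKM (-1.72 ± 0.17). Camera gave an adjusted p of 2.45e-05 (Benjamini-Hochberg), and adjusted p = 0.506 with an estimated correlation. With DESeq2's size factors over the listed genes 24 of the 55 falls passed, the median was -0.34 and 4 genes changed sign (7 with median-ratio scaling). With TMM 48 of the 55 falls passed and with quantile normalization 53. The red blood cell genes had a median of -1.34 in these libraries. The 3 tested matches to mitochondrial respiration fell, of which 2 are respiration genes by name. Among the 2 was sdhb (LOC110492247) of succinate dehydrogenase, from 9.68 ± 0.869 to 3.08 ± 0.0950 FPKM (-1.65 ± 0.15). Of the 2 matches to cytosolic ribosomal proteins 1 rose and 1 fell, and neither is a ribosomal protein by name.

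**Figure D2:**
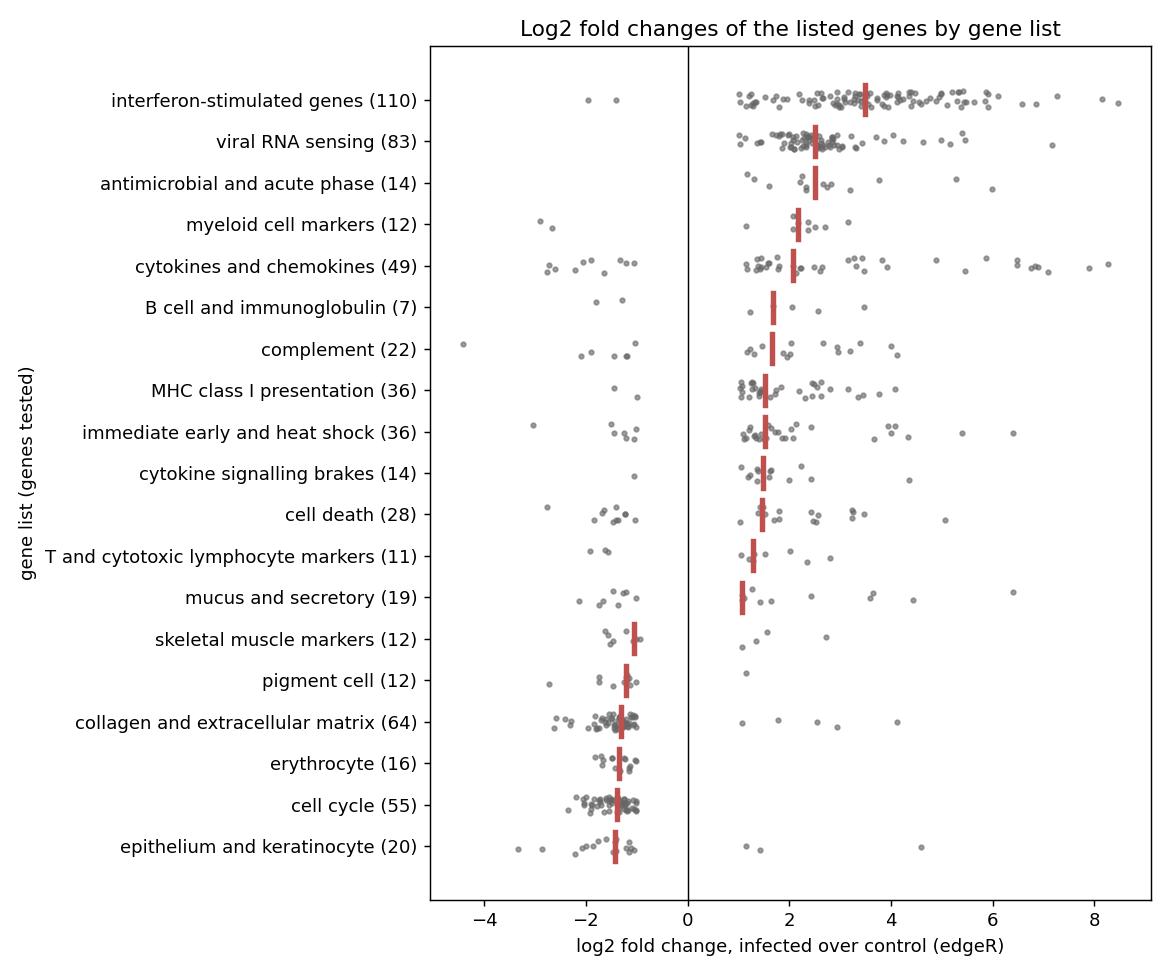
Log2 fold changes (infected over control, edgeR, x axis) of the tested members of 19 gene lists (y axis, number tested in brackets), with points for genes and red lines for medians. The interferon-stimulated list has the highest median (3.50), and the gap around 0 comes from the authors' selection of genes; with DESeq2's size factors over the listed genes fewer falls passed in each list that had any, except the myeloid list.

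Markers of other cell types moved with infection too. All 16 red blood cell genes listed fell, with a median log2 fold change of -1.34 and 16 of 16 lower in infected skin. They included 12 hemoglobin genes, the most abundant of which (hbb, LOC110486352) fell from 361 to 178 FPKM (-1.02 ± 0.17), and the anion exchanger slc4a1 (LOC100136955), which fell from 4.57 ± 0.635 to 1.39 ± 0.270 FPKM (-1.70 ± 0.19). The list passed camera (Benjamini-Hochberg adjusted p = 0.0393, and adjusted p = 0.506 with an estimated correlation). It did not pass camera without infected replicate 1 (adjusted p = 0.0714, range over alternatives 3.83e-04 to 0.506). With DESeq2's size factors over the listed genes 2 of the 16 falls passed and 2 genes changed sign (3 with median-ratio scaling). With TMM 12 of the 16 falls passed and with quantile normalization all 16, and no gene changed sign in either. Of 12 myeloid markers 10 rose and 2 fell: Irf8 (LOC110489699), a transcription factor of macrophages, rose from 11.4 ± 1.18 to 58.9 ± 2.92 FPKM (2.36 ± 0.14) and the protease gene mmp9 by 2.37 ± 0.38, while both genes annotated as eosinophil peroxidase fell (LOC110523686, -2.91 ± 0.24, and LOC110509901, -2.66 ± 0.43). The myeloid list passed narrowly (camera, Benjamini-Hochberg adjusted p = 0.0403; adjusted p = 0.506 with an estimated correlation) and in 12 of 20 camera alternatives (0.00676 to 0.528), but not without control replicate 1 (0.0534), infected replicate 1 (0.0803) or infected replicate 2 (0.0506).

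Lymphocyte, muscle and mucus lists did not pass the test against the other listed genes. Of 11 T and cytotoxic lymphocyte matches 8 rose and 3 fell (camera, Benjamini-Hochberg adjusted p = 0.300): granzyme B (Gzmb, LOC110520645) rose by 2.81 ± 0.36, and tcf7 (transcription factor 7, with the symbol Tcf7l2 in the authors' annotation), which acts in T cell development and Wnt signalling, fell from 12.8 ± 0.723 to 3.38 ± 0.416 FPKM (-1.92 ± 0.15). Of 7 B cell matches 5 rose and 2 fell (camera, Benjamini-Hochberg adjusted p = 0.150), a list that passed with no filter (0.0428; range 0.0428 to 0.506). Irf4 (LOC110492403), a factor of lymphocyte activation, rose from 1.99 ± 0.411 to 21.9 ± 1.32 FPKM (3.46 ± 0.18), and the B cell kinase gene btk fell (-1.29 ± 0.16). Of 12 skeletal muscle matches 4 rose and 8 fell (camera, Benjamini-Hochberg adjusted p = 0.452), with a median of -1.05 that turned to 0.0090 with DESeq2's size factors and 0.069 with median-ratio scaling; 2 of the 5 that are muscle genes by name rose (median -1.08, mean 0.10). Parvalbumin (pvalb2, LOC110499196), a calcium-binding protein described there as thymic, rose from 0.850 ± 0.0265 to 5.71 ± 1.40 FPKM (2.73 ± 0.35). It was 1 of the 2 risen genes kept as muscle genes by name, so that count includes a gene not described as a muscle gene. Fast troponin I (TNNI2, LOC110521356) fell from 132 to 62.6 FPKM (-1.08 ± 0.24). Of 19 mucus and secretory matches 11 rose and 8 fell, with a median log2 fold change of 1.07 (camera, Benjamini-Hochberg adjusted p = 0.324). Of the 15 that are secretory genes by name 7 rose and 8 fell, with a median of -1.01 and a mean of 0.35. Mucins went both ways: MSTRG.44855, a mucin-2-like gene, rose from 2.81 ± 0.986 to 33.7 ± 7.83 FPKM (3.58 ± 0.26), and another mucin-2-like gene, LOC110531777, fell from 29.4 to 6.69 FPKM (-2.13 ± 0.20). Of 12 pigment cell matches 11 fell and 1 rose (camera, Benjamini-Hochberg adjusted p = 0.0476; adjusted p = 0.326 with an estimated correlation). Only 6 of these are pigment genes by name, of which 5 fell (adjusted p = 0.307); SCARB1 (LOC100136324), a carotenoid and lipid receptor, fell from 4.88 to 1.44 FPKM (-1.75 ± 0.15), and of 2 copies of the melanin enzyme gene DCT LOC110520164 fell (-1.01 ± 0.14) and LOC110520165 rose (1.14 ± 0.25). The pigment list also did not pass without control replicates 1 (0.0569), 2 (0.0552) or 3 (0.0530) or infected replicate 1 (0.0732), by camera with Benjamini-Hochberg adjustment (range over alternatives 0.0153 to 0.326). With DESeq2's size factors 2 of the 11 falls passed and 1 gene changed sign. With TMM 8 of the 11 falls passed and with quantile normalization 10. In the other lists of cell types at most 3 members changed sign under another scaling.

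Genes named as examples outside the rule for named genes were chosen after their values were seen, as was the division of the sensing list into TRIM25 and other members. Adjusted over the list alone, each list gave the same counts of risen and fallen genes as over all genes tested. Camera here compares a list with other genes that the authors had already selected, and no list passed it with an estimated correlation. Rainbow trout carry many near-identical gene copies, so single members of families such as TRIM25, hemoglobin, hsp70 and the mucins are uncertain where reads can be shared, and symbols are the authors' homolog annotation.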

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

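The adjustment over the authors' tests, the use of limma with pseudocount 1 as an alternative (it had been fixed as the test for a table without counts), the removal of mismatched names and, for gene lists, a mean of at least 5 FPKM, TMM, DESeq2's size factors, pseudocount 0.5, no trend and array weights were chosen only after the result was seen. The 36 named genes kept their direction and passed the threshold under every alternative that tested them. The number of genes changed (5482) fell to 2473 with a mean of at least 5 FPKM, to 3152 with DESeq2's size factors and to 3038 with median-ratio scaling, both over the listed genes; in the order of these settings 1340, 2022 and 2018 rose and 1133, 1130 and 1020 fell. The stricter filter has fewer genes to test, and the scalings centre on genes selected for change. In the other alternatives with all 6 libraries 4915 to 6894 genes changed. Leaving out 1 library gave 5444 to 5460 changed genes, 1977 to 1993 risen and 3467 fallen. With the replicate number as a block 5476 genes changed, 2009 up and 3467 down. Deviations of same-numbered libraries correlated across genes at 0.025, 0.031 and -0.12, and those of differently numbered libraries at -0.22 to 0.20. These values show no pairing by number, but 3 libraries per group are too few to exclude one. Of the gene lists 15 passed camera; 0 passed with an estimated correlation, 8 with a mean of at least 5 FPKM and 9 with TMM. The medians of lists that changed their side of the threshold follow, and the cause was not tested. With an estimated correlation, which leaves medians as they were, the lists lost were sensing (2.50), interferon-stimulated (3.50), MHC class I (1.53), cytokines (2.08), brakes (1.49), antimicrobial (2.50), complement (1.67), myeloid (2.16), epithelium (-1.42), pigment (-1.20), matrix (-1.32), erythrocyte (-1.34), cell cycle (-1.39), heat shock (1.52) and cell death (1.46). A mean of at least 5 FPKM lost cytokines (1.69), brakes (1.60), antimicrobial (2.33), complement (2.01), myeloid (2.12), epithelium (-1.28) and cell death (1.79). TMM lost complement (2.39), myeloid (2.88), epithelium (-0.70), pigment (-0.48), erythrocyte (-0.61) and cell death (2.18). DESeq2's size factors lost complement (2.73), myeloid (3.21), epithelium (-0.36), pigment (-0.14) and cell death (2.53). Median-ratio scaling lost pigment (-0.099), erythrocyte (-0.23) and cell death (1.78), and quantile normalization lost brakes (0.40), complement (1.27), myeloid (1.45) and cell death (0.41). Pseudocount 0.1 lost epithelium (-1.42) and pigment (-1.21), the replicate block lost pigment (-1.22), and removal of mismatched names lost epithelium (-1.40), pigment (-1.17) and cell death (1.39). The B cell list passed with no filter (1.62). By fry, which does not compare a list with other genes, all 19 lists tested passed, among them T (1.29), B (1.68), muscle (-1.05) and mucus (1.07); with mismatched names removed, muscle and mucus did not pass (fry in limma, Benjamini-Hochberg adjusted p = 0.110 and 0.910). The muscle median turned to 0.0090 with DESeq2's size factors and 0.069 with median-ratio scaling, and the mucus median to -1.01 with no filter and -1.01 with mismatched names removed; neither list passed camera there. Leaving out 1 library lost complement (medians 1.44 to 1.79), myeloid (2.06 to 2.404), epithelium (-1.48 to -1.37), pigment (-1.31 to -1.17), erythrocyte (-1.45 to -1.18) or cell death (1.32 to 1.58) in at least 1 case each. Of listed genes 1416 lie under the filter, 10 of which have over 80% of the higher group's FPKM in 1 library. Among tested genes 1 did so as well, and it was called changed.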

Other observations

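The pathway tests, the tests of matrix, cell cycle and red blood cell genes and the count over other splits were chosen only after the result was seen. Outside the lists, the authors' KEGG annotation placed 1820 tested genes in pathways, of which 256 held at least 10 of them; 80 differed from the other listed genes by camera with a preset correlation, 43 higher and 37 lower in infected skin, and 0 with an estimated correlation (lowest Benjamini-Hochberg adjusted p = 0.649). Wnt signalling genes fell in 69 of 76 cases (median log2 fold change -1.41, camera, Benjamini-Hochberg adjusted p = 0.00106), among them the receptor gene fzd2 (LOC110538204, -2.09 ± 0.22), the ligand WNT7B (LOC110522743, -1.82 ± 0.17) and the inhibitor notum1a (LOC110487055, -2.63 ± 0.24), while the polarity gene vangl2 (LOC110531571) rose by 2.45 ± 0.21. With DESeq2's size factors over the listed genes 30 Wnt genes fell and 4 changed sign (11 with median-ratio scaling). Hippo pathway genes fell in 54 of 57 cases (camera, Benjamini-Hochberg adjusted p = 6.80e-04; 23 fell with DESeq2's size factors, and at most 3 changed sign under another scaling), with TGFB2 (LOC110489077) at -3.10 ± 0.34. All 11 retinol metabolism genes and all 13 genes of xenobiotic metabolism by cytochrome P450 fell (camera, Benjamini-Hochberg adjusted p = 0.0207 and 0.0177), of which 5 and 6 fell with DESeq2's size factors and 0 and 2 changed sign. In the KEGG cell cycle pathway, wider than the cell cycle list, 68 of 74 genes fell and 6 rose (camera, Benjamini-Hochberg adjusted p = 0.00102), and 21 fell with DESeq2's size factors, where 8 changed sign (13 with median-ratio scaling). The cytochrome genes cyp1a3 and cyp1a1 (LOC110526570), targets of the aryl hydrocarbon receptor, fell from 55.0 to 5.75 FPKM (-3.26 ± 0.21) and from 38.0 to 4.34 FPKM (-3.12 ± 0.29).

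In the proteasome pathway 16 of 17 genes rose (median 1.66, camera, Benjamini-Hochberg adjusted p = 1.31e-04; adjusted p = 0.649 with an estimated correlation), including PSMA6 (LOC110503695, 1.79 ± 0.13), a subunit of the alpha ring, and psmb9 (2.62 ± 0.19) of the immunoproteasome; PSME3 (LOC110538407) fell (-1.13 ± 0.14). Under quantile normalization 10 proteasome genes rose and 3 changed sign. In the pathway of protein processing in the endoplasmic reticulum 32 of 42 genes rose (camera, Benjamini-Hochberg adjusted p = 7.24e-06; adjusted p = 0.649 with an estimated correlation; 24 under quantile normalization, where 7 changed sign), among them DNAJB11 (LOC110501845, 3.19 ± 0.16) and the stress sensor Ern1 (LOC110538775, IRE1, 2.16 ± 0.18). Of other pathways, the lysosome had 5 risen and 16 fallen genes and animal autophagy 13 risen and 20 fallen, and neither passed (camera, Benjamini-Hochberg adjusted p = 0.633 and 0.883).

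The fall of matrix and cell cycle genes may come in part from the scaling of the libraries, which moves each gene by the same factor. Over the 114 genes of both lists that fell, log2 fold changes had an SD of 0.36 against a median standard error of 0.19. This was more than a common fold would give (Cochran's Q, n = 114 genes, p = 4.15e-23), but Q takes genes as independent. It cannot tell how much of the falls came from scaling, since unequal changes added to a common shift would scatter as well. The genes had also been selected for falling, and genes that did not change are not analysed here, so scaling stays open. Dilution of skin RNA by RNA of other cells also stays open, since cells that express some of these genes would give unequal folds, and so does infection itself, the difference between the groups.

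All 16 listed red blood cell genes fell, and a candidate explanation is less blood in the infected skin samples, which would lower every such gene by a common fold. Their log2 fold changes, from -1.83 to -1.02 around a weighted mean of -1.33, scattered somewhat more than their standard errors (SD 0.25 against a median of 0.20). This does not exclude a common fold (Cochran's Q, n = 16 genes, p = 0.152), but Q cannot decide the question here. It takes genes as independent, whereas camera estimated a correlation of 0.59 between them. The authors' cut at an absolute log2 fold change of 1 also narrows the scatter. Less blood at sampling, a loss of red cells or of their transcripts through infection, and the scaling of the libraries cannot be told apart. Each could lower these genes by a common fold, and the table holds no unchanged red cell gene. Their median of -1.34 went to -0.27 with DESeq2's size factors and -0.23 with median-ratio scaling over the listed genes. With TMM it was -0.61 and with quantile normalization -2.42.

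Among the listed genes, those that share a symbol mostly moved in the same direction. Pairs with a copy that the authors did not call are not in the table, so the share covers only pairs with both copies listed. Of 548 symbols with 2 tested genes, 485 (88.5%) had both in the same direction, against a mean of 59.2% in 10000 shuffles of the signs (permutation p = 1e-04, the smallest they can give). Reads shared between near-identical copies could give this. In 22.5% of the same-direction pairs the log2 fold changes differed by over 2 standard errors. That is too many for copies that are fully merged and too few to exclude a part from shared reads. Pairs were formed by symbol alone and can hold different genes, such as the IDs cfh and svep1, both with the symbol Svep1. The 22.5% is therefore not a rate for near-identical copies. Shared reads and common regulation cannot be told apart for the same-direction pairs. In the other 63 pairs the genes moved in opposite directions, such as Cd9 (LOC110486460, 2.74 ± 0.15, and its copy CD9, LOC110496495, 86.7 to 43.3 FPKM), CRY1 (LOC110522881, 2.49 ± 0.15, and LOC110537182, -1.56 ± 0.16) and CCN2 (LOC110532630, 1.03 ± 0.18, and LOC110496714, -2.33 ± 0.17).

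The real split of the 6 libraries gave 5482 changed genes and was the only 1 of the 10 splits into 3 and 3 to give as many; the highest of the others gave 1. With 10 splits no share under 0.05 can be reached, and the genes were selected on the real split.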
